A study of Mus musculus with 4 samples.

How the data were processed

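RNA was measured in 4 libraries of mouse mammary tumour cells that carry the polyoma middle T oncogene (PyMT, which drives mammary tumours). Of these, 2 were labelled PCNA WT and 2 were labelled PCNA 211F, a form of the replication clamp named here as the labels name it. Per the labels' protocols, tumours came from mice 10 weeks old, were dissociated, and epithelial cells were captured with an antibody against EpCAM, an epithelial surface protein. The cells were plated at a density of 100000 in medium with serum. Libraries were built with a strand-specific kit and sequenced on an Illumina instrument, per the labels' protocols. The series' design text calls the 2 libraries of each genotype independent biological repeats; whether they came from separate animals is not given in the sources used here, so the p-values measure the spread between these libraries.

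The values used are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), which the authors deposited as a single table of 50679 Ensembl gene identifiers by 4 libraries. TopHat2 2.0.13, DESeq2 and the GRCm38 build are listed in the submitters' processing notes, with no role or order. The program that made the FPKM values, its gene annotation and its treatment of strand are not given in the sources used here. FPKM divides by gene length and by the library total, so a gene with very high expression in a library lowers the values of the others, and overlapping genes can share reads. Symbols were matched by identifier for 50369 genes, and 310 identifiers had no symbol, of which 23 were among the genes tested. Positions are those of GENCODE M21 on GRCm38.

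The table holds no read counts. FPKM sums were 544399 in WT 1, 548742 in WT 2, 564977 in 211F 1 and 551306 in 211F 2. In 1971 genes with a single annotated transcript of at least 3000 bp, low values fell on whole steps, within 0.1 of a fragment, for 95.6% of the values in WT 2 and up to 97.9% in 211F 1. The step was worth 0.0285 FPKM in 1 kb in WT 1, 0.0166 in WT 2, 0.0262 in 211F 1 and 0.0303 in 211F 2. If the values were not rescaled between libraries, this puts the depth relative to WT 1 at 1.72 for WT 2, 1.09 for 211F 1 and 0.940 for 211F 2. Whether they were rescaled is not known. A value of 3 fragments in 1 kb equals 0.0499 to 0.0910 FPKM, and levels near or below that are read as near 0.

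Values were analysed as log2(FPKM + 1), and every difference is 211F minus WT on that scale, which understates the change of low genes. Genes with a mean of at least 1 FPKM over the 4 libraries were tested (12767 genes) with limma 3.58.1 in R 4.3.3, as a two-sided test with an intensity trend in the prior variance and Benjamini-Hochberg adjustment at 0.05. Gene lists were tested with camera in limma, with a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera with an estimated correlation uses only the few residual degrees of freedom of 4 libraries. Hardly any list could pass the adjusted test in that form, so a call lost there decides little on its own. A high estimated correlation does count against a call, since the preset of 0.01 then makes camera's p too small. The test design, the 32 gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. The lists cover PCNA partners, replication, repair, p53 and cell cycle genes, innate immunity, metabolism and signalling. They also cover mammary epithelial states and markers of fibroblast, endothelial, myeloid, lymphoid and adipocyte cells. Of the 32 lists, 30 had at least 3 measured members and were tested.

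The rule for named genes took Pcna and Epcam whatever their values. It then took up to 12 genes in each direction that passed the threshold with groups that did not overlap, and filled empty places with the non-overlapping genes of smallest unadjusted p. Predicted, clone-named, mitochondrial, small RNA and pseudogene symbols were left out of that part. Up to 4 members of smallest p were eligible from each list. Other genes named in the text, among them most of the markers of cell state, were chosen after their values were seen. Some genes that the rule took are not reported here.

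The gene and list tests were run on simulated data for the comparison of 211F with WT. In them 200 genes drawn at random were changed, and the interferon-stimulated list was shifted by 1 log2 unit. Drawn genes in that list or under the filter are left out of the counts below. With the real spread the shifted list had a camera adjusted p of 4.43e-15 and 0 other lists were called. Noise was drawn independently for each gene, so this does not test camera on genes that vary together. With the spread of the real libraries, in a run on 12461 genes, 0% of 73 genes changed by 1 log2 unit were called, 4.76% of 63 changed by 2 and 63.5% of 63 changed by 4, with 6 false calls. This spread was limma's moderated variance, in which each gene's variance is drawn toward the trend, and it held no shift shared between genes. The shares called need not hold for the real libraries, where Tfap2b differed by 4.40 log2 units and did not pass. With a residual SD of 0.1 in every gene, in a run on 12449 genes, 100% were called at each size, with 6 false calls. Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, rescaling to TPM, median centring, quantile normalization, no trend, a robust prior, the replicate number as a block, an estimated correlation and leaving out each library. A covariate for epithelial level and a comparison of WT 1 with 211F 2 alone were chosen after seeing the data. Further steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.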

Results

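Transcript levels were compared between PyMT mammary tumour cells with wild-type PCNA (n = 2) and with PCNA 211F (n = 2). PCNA is the sliding clamp that holds DNA polymerases on their template. The comparison asks which transcripts differ between tumour cells of the 2 genotypes. Between 20468 genes (211F 2) and 22440 genes (WT 2) had a value above 0, and between 11902 (211F 2) and 12278 (211F 1) reached 1 FPKM.

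Epithelial transcripts were abundant in WT 1 and 211F 2, lower or mixed in 211F 1, and nearly absent from WT 2. Cdh1 (E-cadherin) stood at 257 FPKM in WT 1, 0.533 in WT 2, 102 in 211F 1 and 202 in 211F 2. The keratin Krt8 stood at 433, 0.828, 505 and 582 FPKM in the same order, and Krt14, a basal keratin, at 1058, 2.41, 1297 and 1722. Vim, the mesenchymal intermediate filament vimentin, was at 1634 FPKM in WT 2 and 1856 in 211F 1, against 124 in WT 1 and 1.86 in 211F 2. The collagen gene Col1a1 reached 437 FPKM in WT 2 and at most 2.70 in the other libraries. Smooth muscle actin, Acta2, was highest in 211F 1 at 442 FPKM, with 95.8 in WT 2, 0.600 in WT 1 and 0.0739 in 211F 2. Ptprc, the pan-leukocyte antigen, was at or below 0.0180 FPKM in all 4 libraries. These markers were chosen after their values were seen.

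**Figure D1:**
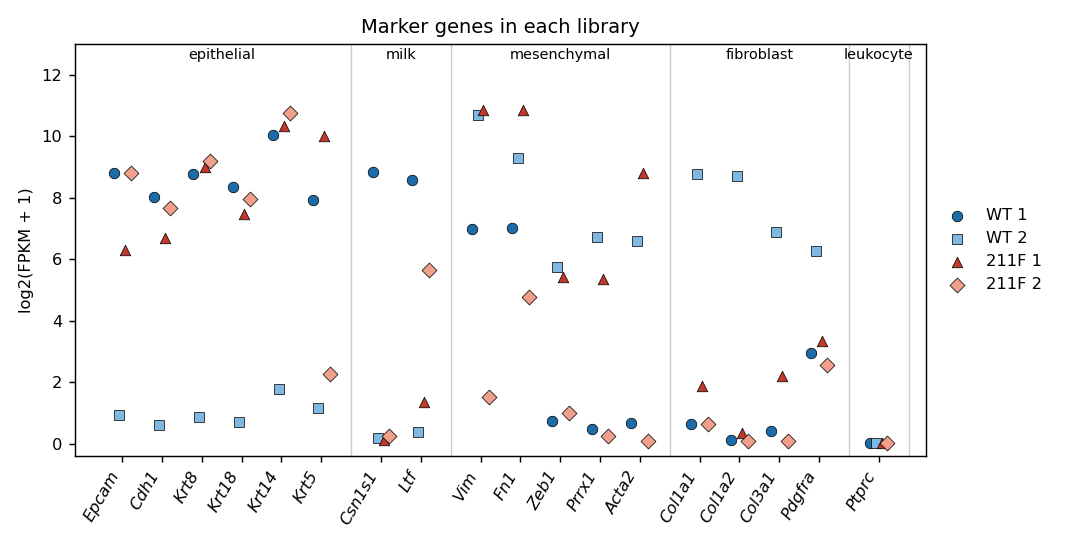
Levels of marker genes as log2(FPKM + 1), one point per library and no error bars, grouped by the cell type or state each gene is known for. WT 2 lies near 0 for the epithelial genes, where Cdh1 is 0.533 FPKM, and 211F 1 is high for both Krt8 (505 FPKM) and Vim (1856 FPKM).

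The libraries did not group by genotype. Across the 12767 tested genes, which are not independent replicates, the highest Pearson r was between WT 1 and 211F 2 (0.920), against 0.748 between both WT libraries and 0.838 between both 211F libraries. WT 1 and WT 2 differed by at least 1 log2 unit in 3124 genes, 211F 1 and 211F 2 in 2433, and WT 1 and 211F 2 in 1324. The first principal component held 62.2% of the variance and set WT 1 (-55.1) and 211F 2 (-62.8) against 211F 1 (26.7) and WT 2 (91.2).

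**Figure D2:**
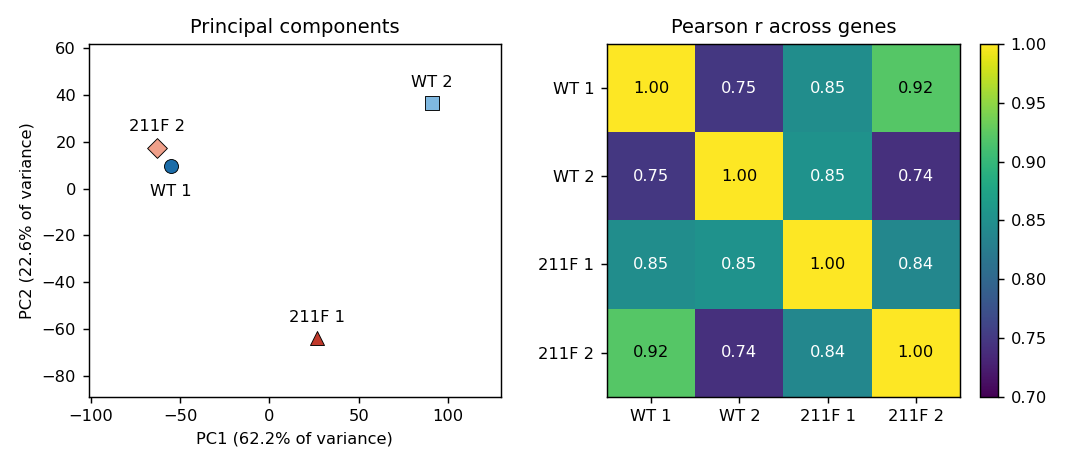
Left, the scores of each library on the principal components PC1 (62.2% of variance) and PC2 (22.6%), in units of log2(FPKM + 1); right, Pearson r across genes for each pair of libraries, on a colour scale from 0.7 to 1. WT 1 lies beside 211F 2 (r = 0.920) and away from WT 2 (r = 0.748).

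Pcna (ENSMUSG00000027342; GRCm38 chromosome 2, 132249162 to 132253314, minus strand) was at 151 ± 5.64 FPKM in WT and 146 ± 38.1 in 211F (mean ± SD, n = 2 each). Its difference was -0.07 ± 0.27 (SE; limma adjusted p = 0.9999), less than the spread between replicates. The allele changes the protein, so this level does not check the genotype labels. Epcam (ENSMUSG00000045394; chromosome 17, 87635979 to 87651129), the antigen used for capture, was at 444 FPKM in WT 1, 0.893 in WT 2, 77.3 in 211F 1 and 450 in 211F 2. The Epcam difference was 2.70 ± 2.92 (SE; limma adjusted p = 0.9999).

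No gene passed the test between the genotypes. The genes given next were taken by a rule that requires both WT libraries to lie apart from both 211F libraries. Their separation is therefore fixed by the choice and does not point to the genotype. Fewer genes were separated in this way than chance gives (26.8% against 33.3%). Adam12, a membrane metalloprotease, was at 5.61 and 4.65 FPKM in WT and 49.0 and 50.01 in 211F, a difference of 3.05 ± 0.26 (SE). Tubb3, a neuronal-type beta tubulin, was at 1.23 and 0.935 FPKM against 19.6 and 32.2 (3.65 ± 0.40). Tfap2b, an AP-2 transcription factor, was near 0 in both WT libraries (0.0155 and 0.0167 FPKM) and at 32.6 and 12.6 FPKM in 211F. Txnip, which restrains glucose uptake, was at 98.1 and 109 FPKM in WT against 14.0 and 21.4 in 211F (-2.51 ± 0.30). Lbp, the lipopolysaccharide-binding protein, was at 60.3 and 44.3 FPKM against 1.65 and 5.30 (-3.69 ± 0.53).

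The limma test called 0 genes higher and 0 lower, and the smallest adjusted p was 0.9999. At an unadjusted p under 0.05 there were 241 genes (114 higher, 127 lower), against 638 expected by chance; without 211F 2 the balance was 209 higher to 78 lower, and without WT 2 it was 124 to 219. The groups did not overlap in 3420 genes (26.8%; 1935 higher, 1485 lower), below the 33.3% that chance gives for 2 against 2. In 37 genes higher and 70 lower, all 4 pairs of a WT with a 211F library differed by at least 1 log2 unit. An exact permutation test of 2 against 2 cannot go below p = 0.333 (two-sided).

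The other genes taken by the rule did not pass either. Higher in both 211F libraries were Odc1, the first enzyme of polyamine synthesis (43.8 and 42.5 against 97.1 and 107 FPKM) and the splicing regulator Mbnl1 (99.8 and 111 against 220 and 233). Emp1, Ajuba, Pstpip2, Fmnl1, Sema4f and Slfn3 lay in the same direction, with differences from 1.11 for Emp1 to 3.04 for Fmnl1. Slfn3 belongs to a family of close paralogs, and exons of Fmnl1 and Pstpip2 overlap a gene on the other strand, so their levels are uncertain. Lower in both 211F libraries were Slc1a3, a glutamate transporter (13.9 and 14.2 against 2.15 and 0.559 FPKM), Map1lc3a, an autophagosome protein (68.6 and 70.7 against 30.1 and 24.0), and Hdac5, a histone deacetylase (37.9 and 37.9 against 15.7 and 17.3). Ypel3, Pltp, Cebpd, Calcoco1, Rgs10, Sord and Pnrc1 lay in the same direction, with differences from -2.21 for Cebpd to -1.21 for Pnrc1. Exons of Txnip, Pltp and Cebpd overlap a gene on the other strand, and those of Hdac5 a microRNA gene on its own strand, so reads may be shared.

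**Figure D3:**
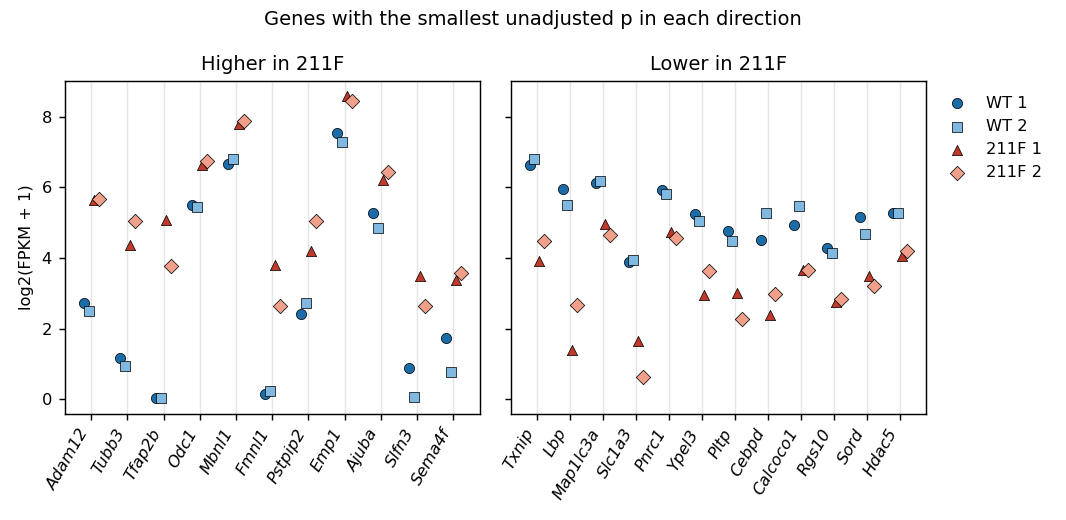
Genes taken by the fixed rule and reported here, as log2(FPKM + 1), one point per library and no error bars; left, those higher in 211F, right, those lower. Both 211F libraries lie above both WT libraries for Adam12 (49.0 and 50.01 against 5.61 and 4.65 FPKM) and below them for Txnip (14.0 and 21.4 against 98.1 and 109 FPKM), and none passed the adjusted test.

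Genes of glycolysis and the hypoxia response were lower in 211F as a group: 26 of 30 members had a negative difference, with a median of -0.52. Pdk1, which diverts pyruvate from the mitochondria, was at 43.3 and 51.4 FPKM in WT and 12.3 and 22.1 in 211F (-1.46 ± 0.37, SE). Bnip3, a mitophagy receptor, was at 48.3 and 176 against 20.4 and 26.2 FPKM, and the glucose transporter gene Slc2a1 at 69.4 and 49.97 against 41.7 and 32.8. The camera test gave an adjusted p of 1.2e-05 with the preset correlation and an adjusted p of 0.865 with an estimated correlation (unadjusted p = 0.0288). The median level of the members was 45.8 FPKM in WT 1, 52.7 in WT 2, 41.9 in 211F 1 and 27.1 in 211F 2, so 211F 1 lay close to WT 1. In WT 1 against 211F 2, the pair with the highest correlation and the 211F library with the lowest median, 24 of 30 members were lower in 211F 2, with a median of -0.57; this pair was chosen after seeing the data and carries no test. No member passed over all genes, and 0 passed adjusted over the list alone.

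**Figure D4:**
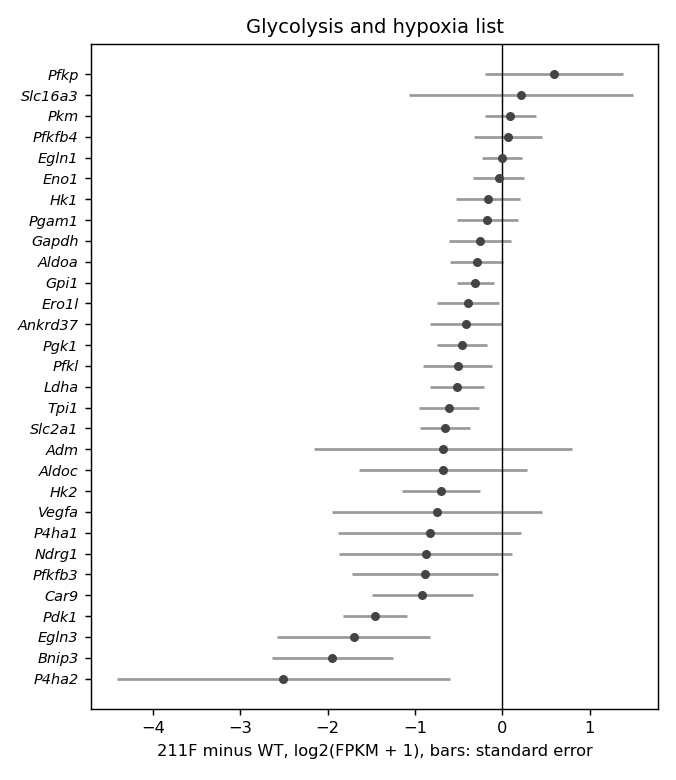
Difference of each of the 30 members of the glycolysis and hypoxia list, 211F minus WT in log2(FPKM + 1), with bars of 1 standard error (n = 2 per group). Of the members, 26 lie below 0, among them Pdk1 at -1.46, and none passed the test alone.

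Cholesterol synthesis genes were higher in 211F as a group, with 16 of 23 members positive and a median of 0.43. Stard4, a sterol transport protein, was at 6.48 and 6.32 FPKM in WT and 9.51 and 14.4 in 211F, and Ebp, a sterol isomerase of the pathway, at 23.2 and 18.9 against 33.1 and 27.4. The camera adjusted p was 0.00902, and the adjusted p was 0.982 with an estimated correlation. That correlation was 0.262, above the preset of 0.01, so the preset p may be too small. Without WT 2 the median was 0.04 and the adjusted p 0.924, so the call rested on that library.

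The other 4 lists that camera called are of cell types and states, and each call ended without at least 1 library. Epithelial junction genes had 25 of 28 positive differences (median 1.5, adjusted p = 0.00902). Their median level was 47.8 FPKM in WT 1, 0.220 in WT 2, 16.3 in 211F 1 and 45.7 in 211F 2, and without WT 2 the direction turned (median -0.90, adjusted p = 0.00418). Fibroblast markers had 11 of 13 negative differences (median -2.15, adjusted p = 0.0123), with Col1a2 at 416 FPKM in WT 2 and at most 0.286 elsewhere; without WT 2 the median was 0.31. Milk protein and secretory genes had 8 of 10 negative (median -1.25, adjusted p = 0.0121), with the casein gene Csn1s1 at 458 FPKM in WT 1 and at most 0.195 elsewhere; without WT 1 the median was -0.01 (adjusted p = 0.616). Of 15 endothelial markers only 3 reached the expression filter, and these 3 were negative (median -1.49, adjusted p = 0.0317). The median level over all 15 was between 0.029 FPKM (211F 2) and 0.07 FPKM (211F 1), near 0. The endothelial call ended without WT 2 (median -0.435) or 211F 2 (median -0.97). The epithelial call also ended without 211F 2 (adjusted p = 0.401) and the milk call without 211F 1, where the median stayed near that of all libraries (-1.12, adjusted p = 0.0503). The fibroblast call ended without 211F 2, where camera's direction turned (adjusted p = 0.525), and with no filter on low genes (adjusted p = 0.0594), as did the endothelial call (adjusted p = 0.342). With an estimated correlation each of these 4 had an adjusted p of 0.982. That correlation was 0.771 for the epithelial, 0.735 for the fibroblast, 0.455 for the endothelial and 0.426 for the milk list. At such values the preset of 0.01 makes camera's p too small, so these calls are not firm. No list passed fry, and 0 members of any list passed adjusted over the list alone.

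Lists tied to PCNA function, repair and the cell cycle were not called in the test as designed. Of 41 DNA replication genes 16 were positive and 25 negative (adjusted p = 0.869), and PCNA-interacting factors were split 15 to 15 (adjusted p = 0.998). Usp1, the deubiquitinase of PCNA, was at 53.3 and 52.5 FPKM in WT and 70.6 and 67.1 in 211F (0.37 ± 0.20, SE). Mismatch repair genes were split 4 to 4 (adjusted p = 0.988), with Pms1 at 5.56 and 5.60 against 7.97 and 8.21 FPKM. Homologous recombination and Fanconi genes had 11 of 28 positive (adjusted p = 0.702). Replication-dependent histones had 3 of 4 positive (adjusted p = 0.702), with 4 of 19 listed members measured. Among p53 targets 14 of 25 were positive (adjusted p = 0.877); Cdkn1a, the p21 inhibitor that also binds PCNA, was at 3.80 and 1.55 against 12.4 and 5.41 FPKM, while Sesn1, a stress-induced regulator of growth signalling, was at 13.1 and 13.4 against 5.10 and 4.56. Cell cycle genes of G2 and M had 21 of 32 negative (adjusted p = 0.202), with Top2a at 264 and 275 against 202 and 158 FPKM. The G2 and M list was called lower without WT 1 (adjusted p = 0.00167), without 211F 2 (adjusted p = 0.00475) and with quantile normalization (adjusted p = 0.0445); the others of these lists were called in no alternative.

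Innate immune lists were not called in the test as designed. Interferon-stimulated genes were split 20 to 20 (adjusted p = 0.967), with Samd9l at 9.56 and 14.4 FPKM in WT against 23.5 and 19.9 in 211F and Irf7 at 24.0 and 31.3 against 12.1 and 19.6. Of 22 genes of cytosolic nucleic acid sensing 13 were positive (adjusted p = 0.702); Cgas, the cytosolic DNA sensor, was at 3.58 and 6.42 against 11.7 and 12.2 FPKM (1.15 ± 0.39, SE). Antigen presentation by MHC class I had 6 of 18 positive (adjusted p = 0.956), ligands of NK cells and checkpoints 3 of 10 (adjusted p = 0.702), and NF-kB targets 6 of 18 (adjusted p = 0.158). Nectin2, a ligand of lymphocyte receptors, was at 33.1 and 40.1 against 17.4 and 20.2 FPKM. Inflammatory chemokines and cytokines had 13 of 20 negative (adjusted p = 0.073); the neutrophil chemokine gene Cxcl5 was at 481 and 286 against 1.98 and 65.0 FPKM. Interferon-stimulated genes were called lower without WT 1 (adjusted p = 0.0283) and higher without WT 2 (adjusted p = 0.0261). Chemokines and cytokines were called lower without WT 1 (adjusted p = 0.00214), without 211F 2 (adjusted p = 0.0160), with the replicate block (adjusted p = 0.0436) and with a pseudocount of 5 (adjusted p = 0.0390), and NF-kB targets without 211F 2 (adjusted p = 0.00846) and at a mean of at least 5 FPKM (adjusted p = 0.0281).

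The remaining lists were not called in the test as designed. Luminal markers had 13 of 18 positive (adjusted p = 0.702), basal and myoepithelial markers 11 of 15 (adjusted p = 0.228), and stemness markers 13 of 19 (adjusted p = 0.112), with Cd44 at 126 and 139 FPKM in WT against 389 and 175 in 211F. Mesenchymal genes had 17 of 27 negative (adjusted p = 0.528), with Tgfbi at 18.1 and 61.1 against 1.43 and 3.33 FPKM; their median level was 8.60 FPKM in WT 1, 52.3 in WT 2, 54.4 in 211F 1 and 3.32 in 211F 2. Matrix remodelling enzymes had 13 of 22 positive (adjusted p = 0.861), TGF-beta and Wnt targets 13 of 21 (adjusted p = 0.702), and ErbB ligands, receptors and feedback genes 17 of 24 (adjusted p = 0.180), with Epgn at 1.35 and 0.165 against 7.70 and 3.51 FPKM. Genes of ATF4 and the unfolded protein response had 22 of 28 positive (adjusted p = 0.303), oxidative phosphorylation 17 of 30 (adjusted p = 0.702), and dissociation stress genes 13 of 22 (adjusted p = 0.422). Macrophage and myeloid markers had 2 of 5 positive (adjusted p = 0.702), with 5 of 24 listed members measured. Only 1 of 23 lymphoid markers and 1 of 11 adipocyte markers reached the expression filter, so these 2 lists were not tested. Stemness markers were called higher without WT 1 (adjusted p = 0.00267), without 211F 2 (adjusted p = 0.000291), with the replicate block (adjusted p = 0.0436) and at a mean of at least 5 FPKM (adjusted p = 0.0301). Leaving out a library also gave calls for the luminal list (higher without WT 1, lower without WT 2), the mesenchymal list (lower without WT 1 or 211F 1, higher without 211F 2) and the basal list (higher without WT 1 or 211F 2). It gave calls as well for the ATF4 list (higher without WT 2 or 211F 2) and the ErbB list (higher without 211F 2). For the histones and matrix enzymes the median was positive (0.10 and 0.12) while camera's direction was down. For mismatch repair and PCNA-interacting factors the median was negative (-0.01 and -0.02) and camera's direction up, and for DNA replication the mean (0.0047) was positive against a median of -0.05.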

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

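The epithelial covariate and the comparison of WT 1 with 211F 2 alone were chosen after the data were seen; the other alternatives were planned. limma called 0 genes higher and 0 lower in every alternative. The 24 genes that the rule took by p have groups that do not overlap, so most alternatives cannot turn their direction, and the 334 unturned values say nothing of stability. Genes at an unadjusted p under 0.05 numbered 241, but 745 without a filter (more genes tested), 142 with the replicate block and 498 with the epithelial covariate; leaving out each library gave 221 to 836, the highest without WT 1. The balance of directions moved too, to 209 higher and 78 lower without 211F 2 and 124 higher and 219 lower without WT 2. Camera called 6 lists, 0 with an estimated correlation, and 6 to 12 when a library was left out (12 without WT 1, 11 without 211F 2). The glycolysis and hypoxia list was called in 14 of 14 alternatives with the preset correlation (medians -0.55 to -0.34). Where a library is left out, the lone library of its group is assumed to vary like the others. The labels do not say whether replicate numbers pair libraries. The deviations of same-numbered libraries had r = -0.465 across genes. The first principal component, which sets WT 1 and 211F 2 against WT 2 and 211F 1, makes this r negative. It therefore neither shows nor excludes pairing or a shared day. With the block 8 lists were called, which added chemokines and stemness markers. Of the lists not called, 7 were gained without WT 1, 3 without WT 2, 1 without 211F 1 and 8 without 211F 2.

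Camera's direction turned in lists that were not called. PCNA-interacting factors had medians of -0.0209 (pseudocount 0.1), 0.0020 (at least 5 FPKM), -0.0521 (TPM), -0.0370 (median centring) and -0.0318 (quantile normalization). Mismatch repair had -0.0915 (at least 5 FPKM), -0.0392 (TPM) and -0.0098 (replicate block). Interferon-stimulated genes had 0.0112 without a filter and 0.0398 with quantile normalization, which gave -0.0367 for oxidative phosphorylation. Without a filter DNA replication had -0.0528, histones 0.18 and matrix enzymes 0.15. The cause was not tested.

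Leaving out each library turned the direction of these results at least once, by the sign of the difference or by camera, with these ranges. Genes: Epcam -1.24 to 6.63, Col1a2 -8.48 to 0.0903, Pcna -0.34 to 0.20. Epithelial and stromal lists: epithelial junction -0.90 to 3.84, luminal -1.27 to 3.03, basal -0.52 to 3.11, milk -1.93 to -0.0080, fibroblast -3.60 to 0.31, mesenchymal -2.23 to 1.74, myeloid -0.78 to 0.74, matrix enzymes -0.48 to 0.34, stemness 0.19 to 0.72. Immune lists: interferon -0.62 to 0.36, nucleic acid sensing -0.0378 to 0.175, MHC class I -0.50 to 0.41, NK and checkpoint ligands -0.59 to 0.41, chemokines -1.91 to 0.35, NF-kB -0.56 to 0.0846. Genome lists: DNA replication -0.0870 to 0.0853, homologous recombination -0.10 to 0.0857, PCNA-interacting -0.0798 to 0.0689, mismatch repair -0.12 to 0.30, p53 -0.0395 to 0.17, G2/M -0.35 to 0.15, histones -0.46 to 0.51. Others: ATF4 -0.0571 to 0.42, oxidative phosphorylation -0.11 to 0.18, TGF-beta and Wnt 0.0430 to 0.39, ErbB -0.14 to 0.69, dissociation stress -0.0354 to 0.39.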

Other observations

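The tests on WT 2, 211F 1, the share of chromosome 11 genes highest in 211F 2 and the other splits of the libraries were chosen only after the result was seen, as were the genes and the chromosome 11 boundary named here. The GC test, the FOXO list test and the Pcna flank test were written before their own results were seen.

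Some transcripts were far higher in 1 library than in the others. In WT 1, Ltf (lactoferrin) was at 379 FPKM against at most 49.0 elsewhere and Krt19 was at 113 against at most 0.0834. In WT 2, the chemokine gene Ccl2 was at 527 FPKM against at most 6.68 and Lox, which crosslinks collagen, at 399 against at most 24.1. In 211F 1, the prostaglandin synthase gene Ptgs2 stood at 429 FPKM and Krt5 at 1029, against 35.4 and 245 in the next highest library. In 211F 2, Krtdap, a keratinocyte differentiation gene, was at 271 FPKM and the macrophage-associated gene Acod1 at 184, against 36.8 and 12.2. Xist, expressed from the inactive X of female cells, was at 52.8, 0.146, 72.5 and 37.2 FPKM in WT 1, WT 2, 211F 1 and 211F 2, while 4 Y-linked genes were at or below 0.169 in each.

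WT 2 held almost no epithelial transcripts although epithelial cells were captured. Stromal cells mixed with epithelial ones would leave the epithelial genes at a common share, taken here as at least 10% of WT 1. The junction genes of WT 2 stood at a median of 0.275% of WT 1 (quartiles 0.166% and 2.22%). This argues against a mixture with 10% or more epithelial cells. A far smaller epithelial share stays open, since the bound was set after the near absence was seen. A fibroblast culture stays open: 8 of 13 measured fibroblast markers were highest in WT 2, with Col1a1 at 437 FPKM, but Dcn was at 3.72 and Lum at 0.0070, and no marker measured here separates a fibroblast from a tumour cell that has lost epithelial genes. Shifts over whole chromosomes 15 (0.50) and 18 (-0.43) and low Xist (0.146 FPKM) in WT 2 would go with an altered genome. A cultured fibroblast can carry one too, and a part of cell state in the shifts was not tested, so they do not decide. A mislabelled library cannot be told apart either, since no value marks the allele or the animal (Pearson r with WT 1 of 0.748), and loss of epithelial state in culture is an untested biological candidate.

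211F 1 held epithelial and mesenchymal transcripts together, which may come from a mixture of cells or from cells with both programmes. The prediction was that 55 genes abundant in WT 2 and scarce in WT 1 and 211F 2 would stand in 211F 1 at a common share, within a 4-fold span, if 211F 1 held cells like WT 2; the span was 119-fold. That bound was wrong, because 82 genes abundant in WT 1 spanned 32.1-fold in 211F 2, the library most like it, so the span does not decide. A second measure, chosen after both spans were known, restates the same spread (27 of 55 genes over 4-fold from the median ratio, against 14 of 82) and decides nothing either. A mixture cannot be told apart from cells with both programmes; Vim was at 1856 FPKM against 1634 in WT 2, and Col1a1 at 2.70 against 437.

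Genes of distal chromosome 11 differed together between the libraries and were highest in 211F 2. From 110399122 to 121716306 (GRCm38), 143 genes with a mean of at least 5 FPKM lay at a median of 1.51 log2 units above the median of the other libraries in 211F 2 and 0.72 above it in WT 1, and at -0.67 in WT 2 and -0.96 in 211F 1. The 211F 2 level was 1.74-fold that of WT 1, WT 1 was 1.70-fold WT 2 and 2.09-fold 211F 1, and 74.8% of the 143 genes were highest in 211F 2, against 27.1% of 9899 genes at that level; this share follows from the median and tests nothing further. A trend on GC content and length is argued against as the whole cause in 211F 2, where the median was 1.47 after removing it. Copy number differing between several of the libraries, not an extra copy in 211F 2 alone, is a candidate explanation that no DNA value here tests. The high libraries, WT 1 and 211F 2, were also those with the most Epcam (444 and 450 FPKM, against 0.893 in WT 2 and 77.3 in 211F 1). A contribution of cell state to the pattern was not tested either.

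Shifts over whole chromosomes were smaller: 0.50 for chromosome 15 in WT 2 (68.2% of 399 genes highest there), 0.40 for chromosome 12 in 211F 2 (60.8% of 329 genes), and -0.43 in WT 2 and 0.34 in 211F 2 for chromosome 18 (251 genes). Chromosome 12 lay at -0.28 in WT 2. In WT 1, chromosome 7 genes lay at 0.58 from 130000001 to 140000000 and at 0.61 from 140000001 to 150000000. Neither copy number nor cell state was tested as a cause of these shifts.

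The 4 libraries make 3 splits of 2 against 2, too few for a share under 0.05. The genotype split separated 107 genes by at least 1 log2 unit in all pairs, the split by replicate number 94 and the remaining split 991, so 2 of the 3 splits, the genotype split included, gave at least 107. The split with 991, WT 1 and 211F 2 against WT 2 and 211F 1, called 9 genes in limma and points to a structure of the samples other than genotype. Camera called 7 lists in it and 12 in the split by replicate number, so 6 lists is not a high number here. The glycolysis and hypoxia list had a camera adjusted p (limma) of 1.2e-05 by genotype, 0.663 by replicate number and 0.332 in the remaining split. With an estimated correlation the genotype call was lost (adjusted p = 0.865).

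Of 2 hypotheses about the genotype, 1 met its prediction, on an unadjusted p for a single added list. Txnip, Sesn1, Ypel3 and Pnrc1, lower in 211F, are known to respond to FOXO factors or to growth arrest, which led to a list of 23 other FOXO targets: 20 were lower in 211F (median -0.43; camera unadjusted p = 2.09e-05, unadjusted p = 0.0424 with an estimated correlation), and 3 of the 23 had an unadjusted limma p under 0.05. The glycolysis and hypoxia list had a smaller unadjusted p with an estimated correlation (0.0288) and lost its call once adjusted over 30 lists, so the FOXO result is no firmer. Gabarapl1 was at 102 and 69.5 FPKM in WT against 34.6 and 43.8 in 211F, and Ccng2 at 34.9 and 43.6 against 12.9 and 23.2. Without WT 1 the p was 0.0536, and without each of the others 4.74e-05 to 0.00134; the other splits gave 0.239 and 0.468. Lower FOXO activity in 211F cells is thus a hypothesis whose prediction was met, but it was found and tested on the same 4 libraries. The list also holds the factor genes Foxo1 and Foxo3. Growth state of the cultures was not tested, so FOXO activity cannot be told apart from it here. The other hypothesis, that genes flanking the Pcna allele differ because they were carried with it, did not meet its prediction. Of 114 genes within 10 Mb, 3 (2.63%) had an unadjusted p under 0.05, against 238 of 12653 elsewhere (1.88%, Fisher exact p = 0.478). So few genes reached that p anywhere that a modest excess near Pcna could not have been found, and carried genes are not excluded.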
